A study of Nitrosomonas europaea ATCC 19718 with 12 samples.

How the data were processed

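Total RNA from 12 cultures was labelled with Cy3 and hybridised to NimbleGen arrays, 1 colour and 1 array per culture. The design text gives 3 chips of 4 arrays and 14 probes per gene, each spotted 2 times. The files hold 66304 gene spots and 5733 random control spots on each array, 72037 in all, for 2368 gene IDs numbered up to 2461, with 93 numbers not used. Samples were grouped by strain and medium as the labels state them, with 3 arrays in each of 4 groups, from separate cultures according to the labels.

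The deposited scanner files hold 1 intensity per spot on a linear scale, extracted with NimbleScan 2.4.31 per the file headers, with no normalization recorded. Their column for mismatch probes is 0 throughout. The value table deposited by the authors holds 1 linear intensity per gene and array; the submitters' processing notes name RMA, without a version, and nothing else about how it was made is given in the sources used here. Its columns have medians of 741, 743 and 730 for wild-type Fe-replete, 731, 733 and 734 for wild-type Fe-limited, 749, 731 and 727 for mutant Fe-replete and 732, 729 and 718 for mutant Fe-limited replicates 1, 2 and 3. On the log2 scale each column correlated with the array of the same label at r from 0.982 to 0.996, with the same direction and no centring of genes. After each gene was centred, 9 columns matched their own scanner file best, with r from 0.956 to 0.982. The 3 mutant Fe-replete columns did not. Column 1 matched scanner file 2 (r = 0.972, its own 0.471), column 2 matched file 3 (r = 0.970, its own 0.707) and column 3 matched file 1 (r = 0.980, its own 0.566). All lie in 1 group, so comparisons of groups are not touched, but the replicate numbers of that group differ between the scanner files and the table. Numbers here are those of the scanner files.

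Spot intensities were background corrected with limma's normexp method and an offset of 50, fitted on all spots, and gene spots were then quantile normalized between arrays. The log2 values of repeat spots were averaged, and the 14 probes of a gene were summarised by median polish. A linear model with the 4 groups was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, which leaves 8 residual degrees of freedom. All 2368 genes were tested, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. All p-values are from this model and are two-sided. A gene was taken as not above background on an array when the median of its spots lay under the 95th percentile of the random controls. Where this held for all arrays of a group, the fold change is a lower bound under this processing. It was computed against the higher of the gene's own value and the lowest value of a gene above the controls on each array. Sampling error is not part of it. The number of arrays limits the precision; intervals are 95% intervals of the model.

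On simulated data for the wild-type comparison, with 50 genes changed at each size among 2368, the fit recovered 48% of changes of 0.5 log2 units, 96% of those of 1 unit and 100% of those of 2 and 3 units. It called 9 of 2168 unchanged genes. The simulated noise was independent between genes and arrays, with no background step and no difference between chips or in brightness. These rates do not cover such differences in the real arrays.

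The comparisons were Fe-limited against Fe-replete in each strain, the strains against each other in each medium, and the difference between the strains' responses. The tests, the groups and the rule for named genes were fixed before the data were examined. The rule would name fur with its neighbours and family, the 10 largest rises and 10 largest falls with adjusted p under 0.05 and no overlap between the groups' arrays (5 each way for the difference of responses), and members of gene lists by pathway. The files do not pair IDs with gene names, so the lists could not be formed, the fur gene could not be checked, and 2 IDs each way per comparison are printed from the top of the rule's ranking.

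The arrangement of arrays on chips was inferred from runs of consecutive image numbers in the file headers. These runs were cut into sets of 4, the number of arrays per chip in the design text. The upper left grid corners lie at 77.2 to 78.1, 85.3 to 88.3 and 58.4 to 60.8 pixels in the 3 sets. A boundary inside a run therefore rests on that cut and the grid corners. By the headers, the arrays of chips 1 and 2 share 1 day, and those of chip 3 have another. Chip 1 holds the 3 wild-type Fe-replete arrays, chip 2 the 3 mutant Fe-limited arrays and chip 3 the 3 wild-type Fe-limited arrays. Each also holds 1 mutant Fe-replete array, replicate 2 on chip 1, 3 on chip 2 and 1 on chip 3. Chip can therefore be fitted as a block, but only through those single arrays. Median random control intensities were 205 to 240 on chip 1, 311 to 321 on chip 2 and 230 to 248 on chip 3.

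Alternatives were other background corrections, median scaling, cyclic loess, the mean over probes, the authors' table, leaving out the dimmest 25% of genes, fits of the compared groups alone, trended and robust eBayes, a minimum log2 change of 1, and blocks for replicate number and chip. Each array was also left out in turn. Chosen after seeing the data were a covariate for array brightness (the log2 ratio of the median gene spot to the median random spot), the 7 lower or the 7 upper probes of each gene by position, the table's numbering in the replicate block, genes above the controls on all arrays, and fits within 1 chip.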

Results

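Transcript levels of 2368 genes were measured in Nitrosomonas europaea, a bacterium that lives by oxidizing ammonia to nitrite. Wild-type cells and a mutant strain, pFur::Kan, were each grown in Fe-replete medium, with 10 µM iron, and in Fe-limited medium, in which about 0.2 µM iron remained. The mutant carries a kanamycin resistance cassette in the promoter region of fur, the gene of the ferric uptake regulator, a protein that in many bacteria binds iron and then represses genes of iron acquisition. Each of the 4 groups holds 3 arrays, each from RNA of a separate culture according to the labels. Fe-replete cultures were harvested at an optical density of 0.04 and Fe-limited cultures at 0.025. Medium and density at harvest therefore changed together in each comparison between media.

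The files identify each gene by an ID and do not pair the IDs with gene names, so genes are given by ID, at most 2 that rose and 2 that fell in a comparison. The level of fur itself is for the same reason not reported. Signal over background differed between groups. The median gene spot was 4.93 to 11.1 times as bright as the median random-sequence control spot in the wild-type Fe-limited arrays. That ratio was 2.34 to 3.49 in the wild-type Fe-replete arrays, 3.30 to 3.92 in the mutant Fe-replete arrays and 2.16 to 2.93 in the mutant Fe-limited arrays. Between 1841 and 2343 genes per array lay above the 95th percentile of the random controls, 1741 genes did so on all 12 arrays and 24 on none. Replicate arrays correlated across genes with r from 0.976 to 0.993, and the median SD of a gene between replicates was 0.12 to 0.16 on the log2 scale. The first principal component, with 48.9% of the variance, parted the Fe-limited from the Fe-replete arrays, and the second, with 23.3%, parted the Fe-limited arrays of the 2 strains. The number of arrays, 3 per group, limits the precision of every value below.

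**Figure D1:**
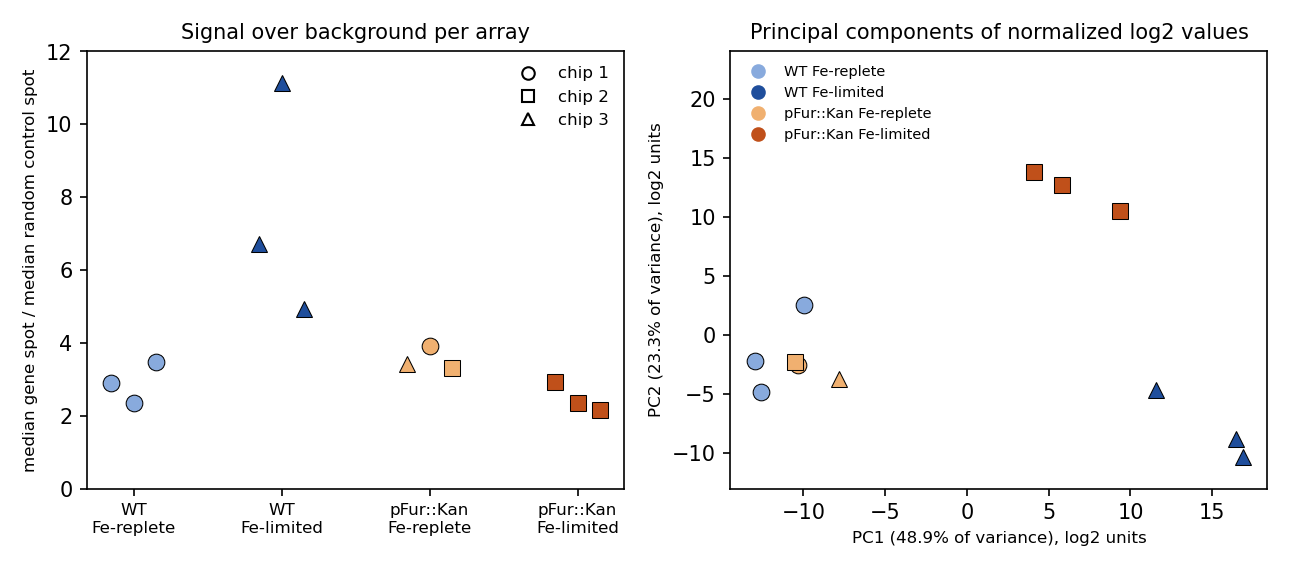
The left panel plots, for each of the 12 arrays, the median intensity of gene spots divided by that of random control spots (no unit), and the right panel plots the arrays on the first and second principal components of the normalized log2 values. Colours mark the 4 groups and symbols the 3 chips; the wild-type Fe-limited arrays have ratios from 4.93 to 11.1, above those of all other arrays, and the Fe-limited arrays of the strains lie apart on the second component.

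The first comparison asked how the wild-type responds to iron limitation. Of 2368 genes, 789 changed, 327 of them rising and 462 falling, at a Benjamini-Hochberg adjusted p under 0.05 (limma). The largest rise was that of nitro071200001479, whose normalized log2 intensity went from 7.50 ± 0.13 to 13.87 ± 0.12 (SD, n = 3 each). Its probes were not above the random controls on any Fe-replete array, so the rise was at least 60.5-fold under this processing (limma adjusted p = 8.0e-11). That bound is 5.92 log2 units. Over the alternatives the fitted log2 change ran from 5.60 to 7.61, so the bound depends on the processing. For nitro071200000704 the level went from 9.08 ± 0.16 to 14.27 ± 0.27 (SD, n = 3 each), a rise of 36.7-fold. Its log2 change was 5.20 with a standard error (SE) of 0.16 (limma adjusted p = 7.3e-11).

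The largest fall was that of nitro071200002119, from 13.57 ± 0.52 to 9.44 ± 0.22 (SD, n = 3 each), a log2 change of -4.12 (SE 0.24, limma adjusted p = 1.1e-07). The next was nitro071200001188, from 11.55 ± 0.24 to 8.48 ± 0.60 (SD, n = 3 each), with a log2 change of -3.07 (SE 0.33, limma adjusted p = 1.5e-05). Most changes were small. The median absolute log2 change of the 789 genes was 0.57, and 132 of them changed at least 2-fold, 78 up and 54 down. In 1097 genes (46.3%) the 3 arrays of one medium lay all above the 3 of the other, where chance gives 10%. That 10% assumes no difference between the groups in chip, day or brightness, and these differ here. The share was 38.6% for iron limitation in the mutant, and 17.8% and 44.4% for the strains in Fe-replete and Fe-limited medium. With arrays scaled to a common median in place of quantile normalization, all genes shifted by a median of -0.22 log2 units in the wild-type response and the calls split into 238 up and 910 down. Cyclic loess gave 384 up and 385 down. The wild-type Fe-replete arrays lay on 1 chip and the Fe-limited arrays on another, linked through single mutant arrays. These 2 chips also carry different days in the file headers. With chip as a block the count was 58, 39 up and 19 down, and the median log2 size of the 789 changes went from 0.57 (median SE 0.13) to 0.47 (median SE 0.27). Of the 4 IDs above, nitro071200001188 lost its call under that block, with a log2 change of -2.67 (SE 0.70, limma adjusted p = 0.082); over all its alternatives the adjusted p lay between 3.7e-07 and 0.082. With array brightness as a covariate, chosen after seeing the data, the count was 96, and the median size went to 0.43 (median SE 0.24).

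The same comparison in pFur::Kan asked how the mutant responds to iron limitation. Here 576 genes changed, 270 up and 306 down (limma adjusted p under 0.05). The leading IDs overlapped with those of the wild-type. The level of nitro071200001479 rose from 7.24 ± 0.10 to 12.18 ± 0.58 (SD, n = 3 each). It was again not above the random controls on the Fe-replete arrays, which makes the rise at least 23.2-fold under this processing (limma adjusted p = 4.1e-09). That bound is 4.54 log2 units, and over the alternatives the fitted log2 change ran from 4.13 to 6.32. The level of nitro071200000704 rose by 3.65 on the log2 scale (SE 0.16), or 12.5-fold (limma adjusted p = 4.1e-09). The largest fall was again that of nitro071200002119, with a log2 change of -4.67 (SE 0.24, limma adjusted p = 2.6e-08). It was followed by nitro071200002055, with a log2 change of -2.97 (SE 0.34, limma adjusted p = 7.0e-05), which in the wild-type had changed by -2.31 (SE 0.34, limma adjusted p = 2.2e-04).

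The median absolute log2 change of the 576 genes was 0.55, and 83 of them changed at least 2-fold, 37 up and 46 down. With chip as a block the count was 156, and 154 of the 576 calls were kept; the median log2 size of the 576 changes went from 0.55 (median SE 0.13) to 0.57 (median SE 0.19), and all 576 kept their sign. Within the chip that held all 3 mutant Fe-limited arrays and 1 Fe-replete array the count was 62; the lone array is assumed there to vary like the other 3, and all 4 arrays are also in the main comparison.

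Across all genes the changes upon iron limitation in the 2 strains, which share no arrays, correlated with r = 0.47; genes are not independent replicates. Of the genes called in both strains, 88 rose in both and 107 fell in both, against 37.3 and 59.7 for independent lists of these sizes. Another 58 genes fell in the wild-type and rose in the mutant, against 52.7 for independent lists, and 17 rose in the wild-type and fell in the mutant, against 42.3. With median scaling the correlation was 0.29.

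**Figure D2:**
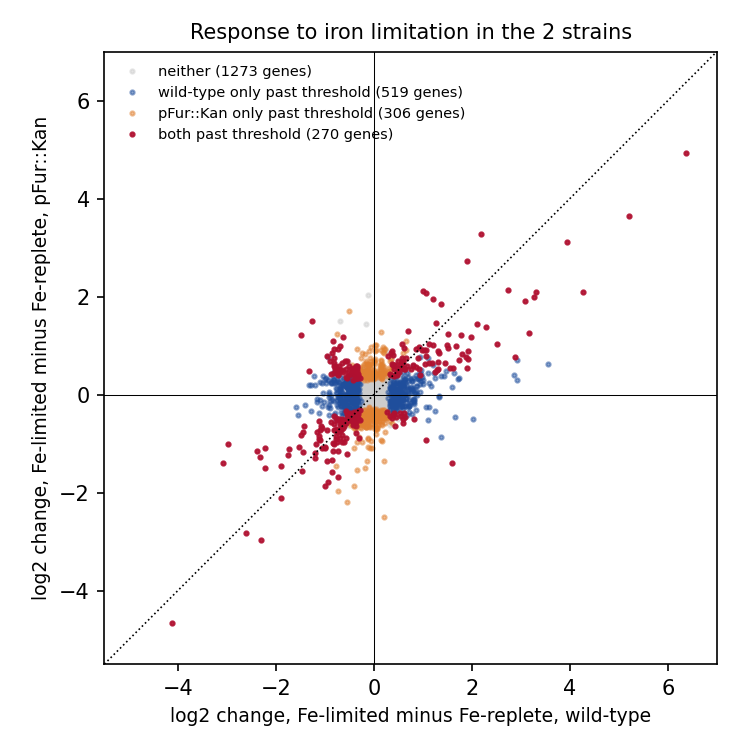
Each point is 1 of 2368 genes, with its log2 change upon iron limitation in the wild-type on the x axis and in pFur::Kan on the y axis; the dotted line marks equal changes. Colours mark the 519 genes past the threshold (limma adjusted p under 0.05) in the wild-type and not the mutant, the 306 in the mutant and not the wild-type, the 270 in both and the 1273 in neither; the points at the upper right and lower left ends are past it in both strains.

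The strains were then compared in Fe-replete medium, where the question is which genes differ when iron is plentiful and the fur promoter is interrupted. Here 11 genes passed the threshold, 8 higher and 3 lower in pFur::Kan (limma), and 240 had an unadjusted p under 0.05. The level of nitro071200000708 was 12.96 ± 0.51 in the mutant and 9.66 ± 0.37 in the wild-type (SD, n = 3 each), 9.86-fold higher (log2 change 3.30, SE 0.23, limma adjusted p = 2.0e-06). The level of nitro071200000709 was 11.42 ± 0.38 in the mutant and 8.73 ± 0.20 in the wild-type (SD, n = 3 each), 6.46-fold higher (log2 change 2.69, SE 0.18, limma adjusted p = 1.8e-06). The remaining 9 changes were smaller. Among the genes lower in the mutant, nitro071200000599 had a log2 change of -0.96 (SE 0.17, limma adjusted p = 0.022) and nitro071200000496 one of -0.86 (SE 0.16, limma adjusted p = 0.022). With chip as a block 2 genes passed, nitro071200000708 and nitro071200000709, while all 11 kept their sign and their median log2 size went from 0.96 (median SE 0.17) to 0.97 (median SE 0.21). Within the chip that held 3 wild-type arrays and 1 mutant array 2 genes passed, which is no separate evidence, since these arrays are in the main comparison too and the lone mutant array gives no spread of its own. Leaving out single arrays gave 4 to 20 genes, 4 without wild-type Fe-replete replicate 2 or without mutant Fe-replete replicate 3; nitro071200000708 and nitro071200000709 passed in each of these fits.

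Of the 8 genes higher in the mutant in Fe-replete medium, 6 also rose upon iron limitation in the wild-type and 1 fell. Of the 3 lower genes, 2 also fell. Independent lists would share 1.10 genes that rose and 0.585 that fell. In the wild-type, nitro071200000708 rose by 3.56 on the log2 scale (SE 0.23, limma adjusted p = 1.6e-07) and nitro071200000709 by 2.92 (SE 0.18, limma adjusted p = 1.1e-07). In the mutant the change upon iron limitation was 0.62 for nitro071200000708 (95% interval 0.12 to 1.13, limma adjusted p = 0.067). It was 0.31 for nitro071200000709 (95% interval -0.08 to 0.69, limma adjusted p = 0.24). Over all genes, the strain difference in Fe-replete medium and the wild-type's response correlated with r = 0.39. These comparisons share the wild-type Fe-replete arrays, and 100 simulations of unchanged groups gave a mean r of 0.504 from that sharing alone (0.425 to 0.590). The observed r lay below all of these. The covariance was 0.0493, against a mean of 0.0140 in the simulations, whose noise was independent between genes. Genes with large changes, such as nitro071200000708 and nitro071200000709, weigh most in a covariance, so the excess need not hold for most genes. With 3 shared arrays no split into parts of 2 or more arrays was possible, so part of the overlap may come from the shared arrays. All 3 lie on chip 1, and the simulations held no chip difference. A deviation of that chip could therefore also add covariance.

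In Fe-limited medium 814 genes differed between the strains, 420 higher and 394 lower in pFur::Kan (limma adjusted p under 0.05), with a median absolute log2 difference of 0.55. At least 2-fold differences were found for 73 of them, 39 higher and 34 lower. The IDs nitro071200001195 and nitro071200001196, which carry consecutive numbers, led the genes higher in the mutant. The level of nitro071200001195 was 12.84 ± 0.37 in the mutant and 9.91 ± 0.71 in the wild-type (SD, n = 3 each), 7.58-fold higher (limma adjusted p = 2.4e-04). That of nitro071200001196 was 13.26 ± 0.36 in the mutant and 10.38 ± 0.78 in the wild-type (SD, n = 3 each), 7.35-fold higher (limma adjusted p = 2.0e-04). Among the genes lower in the mutant, nitro071200002315 had a log2 difference of -2.59 (SE 0.36, limma adjusted p = 3.2e-04). The next, nitro071200000897, had one of -2.38 (SE 0.58, limma adjusted p = 0.0071), with a wide spread in the mutant, 11.36 ± 1.78 (SD, n = 3). Its mutant replicate 2 was at 13.29, near the wild-type mean of 13.75. The SE pools the smaller spreads of the other groups, and a fit of the compared groups alone gave 0.72 (limma adjusted p = 0.039).

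With median scaling all genes shifted by a median of 0.20 log2 units in this comparison and the calls split into 872 higher and 272 lower. The Fe-limited arrays of the strains lay on different chips, whose file headers give different days. With chip as a block no gene passed in limma, 354 had an unadjusted p under 0.05, and the median log2 size of the 814 differences went from 0.55 (median SE 0.13) to 0.52 (median SE 0.27). With array brightness as a covariate, chosen after seeing the data, the count was 23. The 4 IDs above all lost their call under the chip block, with log2 differences of 2.63 (SE 0.80) for nitro071200001195, 2.60 (SE 0.74) for nitro071200001196, -2.66 (SE 0.73) for nitro071200002315 and -2.19 (SE 1.26) for nitro071200000897. Under the brightness covariate nitro071200002315 alone among them passed, at -4.61 (SE 0.47), and nitro071200001196 was at 1.85 (SE 0.69).

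The last comparison asked which genes respond to iron limitation differently in the 2 strains, as the mutant's log2 change minus the wild-type's. The difference passed the threshold for 567 genes, with a more positive change in the mutant for 317 and a more negative one for 250 (limma adjusted p under 0.05). Of the 317 genes, 228 were called as falling in the wild-type and 128 as rising in the mutant, and their median log2 changes were -0.48 in the wild-type and 0.29 in the mutant. Of the 250 genes, 149 were called as rising in the wild-type and 90 as falling in the mutant, with median changes of 0.42 and -0.29. The difference was 2.77 (SE 0.53, limma adjusted p = 0.0035) for nitro071200001195, which fell by 1.26 on the log2 scale in the wild-type and rose by 1.50 in the mutant. For nitro071200001196 it was 2.71 (SE 0.49, limma adjusted p = 0.0027).

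The most negative difference, -2.99 (SE 0.36, limma adjusted p = 4.7e-04), was that of nitro071200000028, with a change of 1.59 in the wild-type and -1.40 in the mutant. For nitro071200000708 it was -2.93 (SE 0.33, limma adjusted p = 3.0e-04). With median scaling the calls split into 758 more positive and 185 more negative, after a shift of all genes by a median of 0.24. With chip as a block no gene passed in limma, and 327 had an unadjusted p under 0.05. The median log2 size of the 567 differences went from 0.74 (median SE 0.19) to 0.68 (median SE 0.33), and 561 kept their sign. With the brightness covariate 10 genes passed, the median size was 0.63 (median SE 0.33) and 554 kept their sign. The 4 IDs above lost their call in both fits and kept their direction; the largest move was that of nitro071200001196, to 1.48 (SE 0.86) with the brightness covariate.

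**Figure D3:**
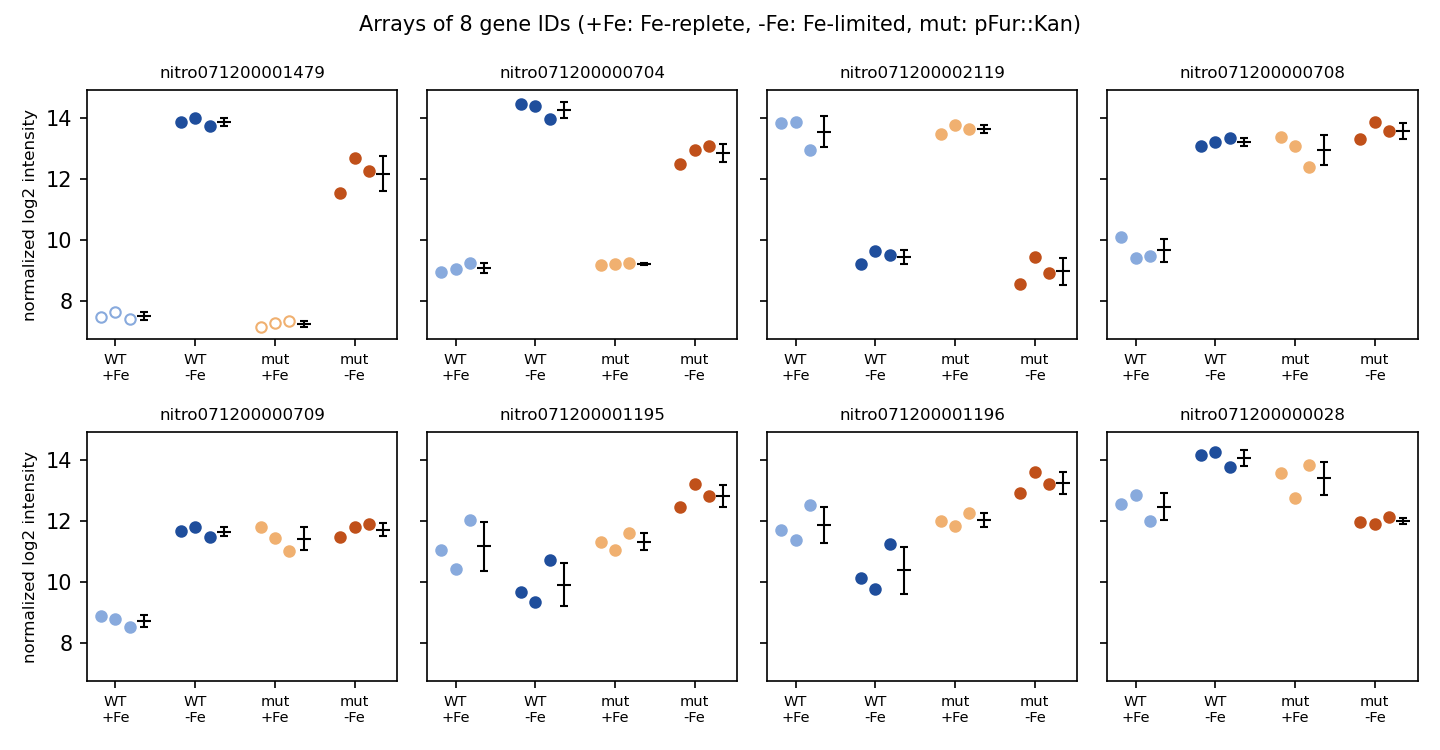
The panels plot normalized log2 intensity on each array for 8 of the gene IDs, with the mean and SD of the 3 arrays of a group beside the points; open points were not above the random controls. The IDs nitro071200001479 and nitro071200000704 are high in both Fe-limited groups, nitro071200002119 is low in them, and nitro071200000708 and nitro071200000709 are low in the wild-type Fe-replete arrays, with means of 9.66 and 8.73.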

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

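The tests of chip and array brightness below, apart from the chip block, were chosen after the results were seen. The chip block and the count over other splits of the arrays were planned. Groups of 3 arrays were not screened for single outlying arrays.

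The response to iron limitation differed between the strains for 567 genes by the interaction term (limma adjusted p under 0.05), and the same term passed for 11 of the IDs printed above. It was negative, a lower change in the mutant, for nitro071200001479 (-1.44), nitro071200000704 (-1.55), nitro071200000708 (-2.93), nitro071200000709 (-2.62), nitro071200002315 (-2.52), nitro071200000897 (-2.70) and nitro071200000028 (-2.99), all in log2 units. For nitro071200001479 this is a fitted value that rests on Fe-replete levels not above the random controls in either strain, so its size is not a measured difference. For nitro071200000897 it rests on mutant Fe-limited arrays with an SD of 1.78. The term was positive for nitro071200001188 (1.69), nitro071200000496 (1.69), nitro071200001195 (2.77) and nitro071200001196 (2.71). Among 100 splits of strain within each medium, the real one included, 1 gave as many genes, the real one with 567. Such splits break up any strain difference in either medium. They therefore cannot exclude chance for the difference of responses itself. The splits do not separate strain from chip, since the Fe-limited arrays of the strains lie on different chips. With chip as a block 0 of the 567 calls remained, while 561 kept their sign. Their median log2 size went from 0.74 to 0.68 and the median SE from 0.19 to 0.33. The highest other split gave 463. It belongs to the 9 drawn splits that left the strain labels of the Fe-limited arrays as they are, which gave 151 to 463 genes, while the remaining 90 gave at most 5; the count follows the structure of the Fe-limited arrays.

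For the 4 comparisons of 2 groups, 6 arrays make 10 splits, too few for a share under 0.05. In fits of those 6 arrays the real split, counted as 1 of 10, gave 766 genes for iron limitation in the wild-type, 496 for iron limitation in the mutant, 26 for the strains in Fe-replete medium and 658 for the strains in Fe-limited medium. The highest other split gave 0 genes in each of the 4. Every other split holds arrays of both groups on both sides, so the group difference adds to its spread. These 0 counts therefore say little about chance.

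The 789 changes in the wild-type upon iron limitation lie between 2 chips, between 2 days in the file headers and between dim and bright arrays. Chip and day are not separated here. If chip were the whole cause, the mutant Fe-replete arrays of the same 2 chips would differ by as much, a slope of about 1 over the 789 genes. The slope was 0.095, with a spread of 0.076 taken from pairs of arrays of 1 chip and group. It rests on the same single mutant arrays as the chip block, so it is no separate evidence. Under that block the changes had a slope of 0.905 on those of the main fit. Genes with large changes weigh most in both slopes. The mutant Fe-replete arrays, on 3 chips, had a median SD over these genes of 0.13, against 0.14 to 0.16 in the groups that lie on 1 chip each, and 0.29 would be the least if chip gave the median change. The 789 genes were called with a spread pooled over all groups, so a low SD over them is partly built in. Over all genes, called or not, the median SD was 0.12 in the mutant Fe-replete arrays. It was 0.14 to 0.16 in the other groups. The change predicted from brightness within groups had a slope of 0.152 on the observed one (jackknife SE 0.059), also far from 1. This slope rests mostly on the bright wild-type Fe-limited arrays. Their log2 brightness had an SD of 0.59, against 0.13 to 0.29 in the other groups. An effect particular to dim arrays could escape it. With brightness as a covariate 94 of the 789 calls were kept and 763 signs, as the median size went from 0.57 to 0.43 and the median SE from 0.13 to 0.24. A part from either stays open, as do iron and the lower density at harvest, which the design does not separate.

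The 814 differences between the strains in Fe-limited medium have the same layout. The chip difference in the mutant Fe-replete arrays had a slope of 0.078 on them (spread 0.13), which argues against chip as the whole cause. That slope rests on the same single arrays as the chip block, and large differences weigh most in it. For brightness the slope was 0.136 with a jackknife SE of 0.26, and it ranged from -0.07 to 0.23 as single arrays were left out, so brightness cannot be told apart from strain here: the wild-type Fe-limited arrays are the bright ones. The strain difference remains open beside it. With the chip block the calls ended since the median SE of the 814 genes went from 0.13 to 0.27 while 801 kept their sign; with the brightness covariate it went from 0.13 to 0.27, 767 kept their sign and the median size went from 0.55 to 0.47.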

How the results depend on the processing

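Across 30 alternatives for the 20 printed changes, 552 of 582 values kept direction and side of the threshold, 30 kept direction only and 0 reversed. Of the 30, 11 fell under the chip block and 7 under the brightness covariate, and 14, some of them among these, concern nitro071200000599 and nitro071200000496. The 0 reversals are partly built in. Fits of the compared groups alone, trended and robust eBayes and leaving out dim genes keep the fitted change by construction. So do the replicate blocks, and leaving out arrays of groups outside a comparison. Under the chip block 9 of the 20 changes kept their call, and under the brightness covariate 13. Counts are given for the wild-type response, the mutant response, the strains in Fe-replete medium, the strains in Fe-limited medium and the difference of responses, in this order. A minimum log2 change of 1 left 132, 83, 5, 73 and 135 by construction. The chip block gave 58, 156, 2, 0 and 0, where standard errors grew because the block rests on single arrays. For the last pair 354 and 327 genes had an unadjusted p under 0.05. As a random block chip gave 1215 for the wild-type response and 20 for the strains in Fe-replete medium, with an estimated correlation of -0.146, below 0. The brightness covariate, added after seeing the data, gave 96, 23 and 10 for the wild-type response, the strains in Fe-limited medium and the difference of responses, and fits within 1 chip, also added, gave 62 for the mutant response and 2 for the strains in Fe-replete medium, with 1 arm of a single array that is assumed to vary like the rest. Median scaling gave 5 for the strains in Fe-replete medium and 943 for the difference of responses. Fits of the 2 groups alone gave 26 for the strains in Fe-replete medium. For these the cause was not tested, nor for the correlations that follow.

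The correlation of the strains' responses (0.47) was 0.29 with median scaling, 0.29 with the brightness covariate and 0.52 without the dimmest 25% of genes. That of the wild-type response with the strain difference in Fe-replete medium (0.39) was 0.46 with median scaling, 0.30 with cyclic loess and 0.42 with the brightness covariate. Leaving out single arrays gave 518 to 881, 392 to 597, 4 to 20, 549 to 838 and 364 to 647 genes, and correlations of 0.42 to 0.51 and 0.30 to 0.46. Shifts over 1.5 times came without wild-type Fe-limited replicate 1 (518 for the wild-type response, 364 for the difference of responses). For the strains in Fe-replete medium they came without wild-type Fe-replete replicates 1 (6) and 2 (4), wild-type Fe-limited replicate 3 (20) and mutant Fe-replete replicates 1 (7) and 3 (4). Apart from the replicate block, given next, all other counts stayed within 1.5 times.

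Replicate numbers were not taken to pair the arrays, since only 10 of 18 same-number pairs had deviations correlated over 0.1, from -0.54 to 0.41. In 23 of 36 cases, 12 by chance, an array correlated best with its own number, which is a hint from the data and not the design. With a replicate block the count for the strains in Fe-replete medium was 21, and 11 with the authors' numbering; the others stayed within 1.5 times. PM minus MM was not run, as the mismatch column holds only 0, and the RMA background used limma's rma75 estimator. The fur gene and the gene lists were not run, for want of names. Signal over background limits the lowest genes: 1841 to 2343 of 2368 lay above the random controls on an array.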

Other observations

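The contrast in this paragraph and the look at neighbouring IDs were chosen after seeing the data; the 2 tests of reasons for the latter were set before their results were seen. The 2 IDs highest in the mutant over the wild-type in Fe-replete medium had there about the level that iron limitation gave them in the wild-type. The mutant Fe-replete arrays minus the wild-type Fe-limited arrays gave -0.26 log2 units for nitro071200000708 (95% interval -0.76 to 0.25) and -0.23 for nitro071200000709 (95% interval -0.62 to 0.16). For nitro071200000704, among the top rises of the iron response, the same difference was -5.07 (95% interval -5.41 to -4.72), and its level in Fe-replete medium differed between the strains by 0.13 (95% interval -0.22 to 0.48). The ID ranked next after nitro071200000709 in Fe-replete medium stayed below its wild-type Fe-limited level. Its means were 13.54 in the mutant Fe-replete arrays and 15.29 in the wild-type Fe-limited arrays.

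Genes with neighbouring ID numbers changed together. The log2 changes of consecutive IDs correlated with r = 0.47 in the wild-type response, 0.50 in the mutant response, 0.40 and 0.45 for the strains in Fe-replete and Fe-limited medium. The highest value in 1000 shuffled orders was 0.109. At a distance of 10 numbers the values were 0.05, 0.0037, 0.04 and 0.09. In the wild-type response 299 pairs of consecutive IDs were called in the same direction, where shuffled orders gave a mean of 132. In runs of 3 or more lay 281 of the 789 genes, against a mean of 59.1, and the longest run of falls held 11 genes and that of rises 10. In the mutant response 192 of 576 genes lay in such runs, against a mean of 22.6.

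Closeness of their probes on the array does not account for this, since the mean distance between probes of consecutive IDs was 1.00 times that of random pairs (SE 0.0013). A hypothesis is that consecutive IDs are transcribed together, as in operons. It predicts that they also deviate together between replicate cultures. Deviations from group means correlated by 0.296 between consecutive IDs, against at most 0.037 in 1000 shuffled orders, which is consistent with that hypothesis. Each culture gave 1 array, so array effects shared by neighbouring genes could give the same correlation, and the test cannot tell these apart. Similar probe sequences in neighbouring genes were not tested, and the files do not pair IDs with positions in the genome.

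The slope of log2 intensity over the relative position of a gene's probes was -0.097 to -0.119 in the mutant Fe-limited arrays, and -0.00306 to -0.026 in the wild-type Fe-limited arrays. In the Fe-replete arrays it lay between -0.067 and 0.016 for the wild-type and between -0.074 and -0.025 for the mutant. The 4 steepest slopes are those of the 4 arrays of chip 2, the mutant Fe-limited arrays and mutant Fe-replete replicate 3 (-0.074), so chip and group are not separated for this pattern. It also runs with the strain difference in Fe-limited medium, and its part in those 814 calls was not tested. With the 7 lower or the 7 upper probes alone, all 20 printed changes kept direction and side of the threshold.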
